A study of Homo sapiens with 16 samples.

How the data were processed

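RNA from T47D cells was measured on 16 single-channel (Cy3) Agilent arrays, 2 per time in control and 3 per time with siNUDIX5 and with TA. Per the labels, 100 ng of total RNA was labelled per array, the cells were starved for 24 h and R5020 was given for 6 h. Each array was deposited as a scanner file of Agilent Feature Extraction (10.7 in the submitters' notes, 10.7.3.1 in the files). Per the file headers its processed signal is an intensity, background subtracted and detrended by the scanner software and not normalized between arrays, and its mean signal and local background are intensity values without correction. The deposited value table is in log2 units, normalized by the authors. Its values matched those of normexp background correction with offset 50 followed by quantile normalization (r = 0.99997, median absolute difference 0.002), centred per feature on a reference that the files do not give. Spot flags in the files are 0 or 1. Probe coordinates are on hg19.

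The processed signal was used. Of 62976 spots per array, 58717 belonged to non-control probes, which made 50599 distinct probes. Spots marked as outliers by the scanner software (258 to 436 per array) were left out, saturated spots numbered 0, and no pair of arrays held identical values. On the log2 scale the 75th percentile over non-control spots was subtracted from each array, and spots of one probe were averaged. Gene names were updated by RefSeq accession for 28174 probes, kept as given for 20511, and 1914 probes were named by probe only. A gene was represented by its brightest probe over all arrays. Genes well above background on at least 2 arrays of 1 group were kept, 21757 of 36619, and the other 14862 were left out as dim. No sample was left out. The 75th percentile of intensity ran from 639.6 to 995.3. Replicates correlated at 0.9669 to 0.9925 across genes, the lowest in TA_T6. The number of arrays limits the precision.

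Groups came from the labels. All 16 arrays entered 1 linear model with a mean per group (limma 3.58.1 in R 4.3.3, default empirical Bayes, 10 residual and 1.62 prior degrees of freedom, data.table in version 1.17.8 for reading, statmod 1.5.0 for random blocks). The 10 contrasts were the R5020 response in each arm, the 3 differences between these responses, and siNUDIX5 and TA against control at 0 h and at 6 h. Genes with a Benjamini-Hochberg adjusted p below 0.05 within a contrast were called. SE is that of limma's coefficient. A gene with no array of a group well above background has a fold between 2 groups given as a lower bound, from the background level. A difference between 2 responses has no such bound, and its size depends on the background where a group is dim. NUDT5, NUDT9 and PARG levels were compared by exact two-sided permutation over the 210 splits of 6 and 4 arrays, pooling both times, and, after the data were seen, again without each array in turn.

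Before the data were examined, 27 gene lists from textbook knowledge were fixed: progestin-induced genes, oestrogen receptor targets, steroid receptors and cofactors, DNA replication and G1/S, mitosis, poly(ADP-ribose) and NAD metabolism, NUDIX hydrolases other than NUDT5, chromatin remodelling complexes, interferon-induced genes, inflammatory NF-kB targets, NRF2 antioxidant targets, integrated stress and unfolded protein response, hypoxia-induced genes, metallothioneins, p53 targets, cholesterol synthesis and uptake, fatty acid synthesis, glycolysis, oxidative phosphorylation, nucleotide kinases and ATP use, immediate early genes, heat shock genes, ribosome biogenesis, luminal markers, basal and mesenchymal markers, stromal and blood cell markers, and housekeeping genes. In the lists, 17 genes stand in more than 1. Lists were tested with limma's camera at its preset correlation of 0.01 and again with the correlation estimated per list, with Benjamini-Hochberg adjustment over the lists of a contrast.

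The genes to name were also set by a rule fixed before the data were examined. Among called genes with a symbol, and for 2 groups no overlap between their arrays, the 12 with the largest positive and the 12 with the largest negative change were taken for the R5020 response in control, the differences of siNUDIX5 and TA responses from control and both arms at 0 h, and the 5 each way for the other contrasts. For TA at 0 h genes that did not pass filled the number, and LOC100506220 was named after its value was seen. List members named as examples, and NUDT9 in the permutation test, were picked after seeing values. The response size ratio was computed over genes called in the third arm. The rule for calling it (Benjamini-Hochberg over the camera p of raised and lowered genes) was set after the data were seen.

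Replicate numbers were checked for pairing by the correlation across genes of residuals of same-numbered arrays. Of 36 such pairs 16 had r above 0.1 (median 0.083, range −0.187 to 0.314). For siNUDIX5 at 0 and 6 h the 3 values were 0.14, 0.204 and 0.314, and for TA 0.081, 0.059 and 0.123. The labels do not state pairing, so no block was used, and a replicate block was an alternative. The arrays lay on 3 slides, which mostly follow the replicate number, and slide was tried as a fixed and as a random block (consensus correlation 0.086).

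The alternatives were quantile normalization, scaling to each array's median, normexp with quantile normalization, the deposited value table, no filter, a filter for all 16 arrays well above background, the mean of a gene's probes, replicate and slide blocks, array weights, a trended robust prior, a fit of the compared groups only, a 1.5-fold minimum and leaving out each array in turn. After the data were seen, scaling to the median of spots above background on every array, and median scaling with TA_T6 replicate 2 left out, were added. Leaving out 1 of 2 control arrays leaves a single array, which is then assumed to vary like the other groups.

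The fit was tested on simulated data with 50 changed genes at each of 4 sizes among 21757. At 2-fold, 46 percent were recovered for the R5020 response in control, 74 percent with siNUDIX5 or TA and 48 percent for a difference of either arm from control. At 8-fold, 84 to 100 percent were recovered in the 10 contrasts. Camera called a shifted list at an adjusted p of 2.01e-16 and 0 of 26 unshifted lists. Genes were simulated as independent, so false calls of lists whose genes vary together were not tested.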

Results

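Expression was measured on 1-colour Agilent arrays in T47D, a breast cancer cell line that carries progesterone and oestrogen receptors. The cells were starved of serum for 24 h and harvested before or 6 h after adding R5020, a synthetic progestin. The labels name a control (2 arrays at each time), an siRNA against NUDIX5 (siNUDIX5, 3 arrays at each time) and tannic acid (TA, 3 arrays at each time). NUDIX5 is the hydrolase NUDT5, which cleaves ADP-ribose, and the title of the series names inhibition of PARG, the enzyme that breaks down poly(ADP-ribose), as the other treatment. The 75th percentile of intensity lay between 639.6 and 995.3 on the 16 arrays. On 15 arrays between 31985 and 35997 probes were well above background. On the remaining array, TA_T6 replicate 2, 42239 were, its median intensity was 124.8 against 38.5 to 59.5 elsewhere, and it had the lowest correlation with a replicate (0.9669). After filtering, 21757 genes were tested. The labels do not say whether replicates were separate cultures, and if they were not, p-values measure only the spread between arrays. They do not say what the control cells received and give neither the dose nor the time of TA. The number of arrays limits the precision.

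The target of the siRNA was compared first. Arrays of 0 h and 6 h were pooled in this paragraph, so each SD includes any difference between times, and the permutations ignored time. With siNUDIX5 the NUDT5 level was 0.58 to 0.89 at 0 h and −0.02 to 0.14 at 6 h. NUDT5 (probe at hg19 chromosome 10, 12214785 to 12214844) had a log2 level of 0.41 ± 0.39 (SD, n = 6) with siNUDIX5 and 4.27 ± 0.02 (SD, n = 4) in control, 14.6-fold lower (exact two-sided permutation p = 0.00476). NUDT9, a related ADP-ribose hydrolase (chromosome 4, 88379293 to 88379352), was also lower, at −0.22 ± 0.17 (n = 6) against 2.06 ± 0.11 (n = 4), 4.88-fold (exact p = 0.00476). It was picked for this test after its values were seen, so that p is descriptive. PARG mRNA (chromosome 10, 51363207 to 51363266) had a level of −1.33 ± 0.53 (n = 6) with TA and −1.17 ± 0.16 (n = 4) in control (difference −0.16, exact p = 0.657). Without TA_T6 replicate 2 the difference was −0.35 (exact p = 0.119), and a second PARG probe differed by −0.32 (exact p = 0.162), so a small difference was not settled.

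**Figure D1:**
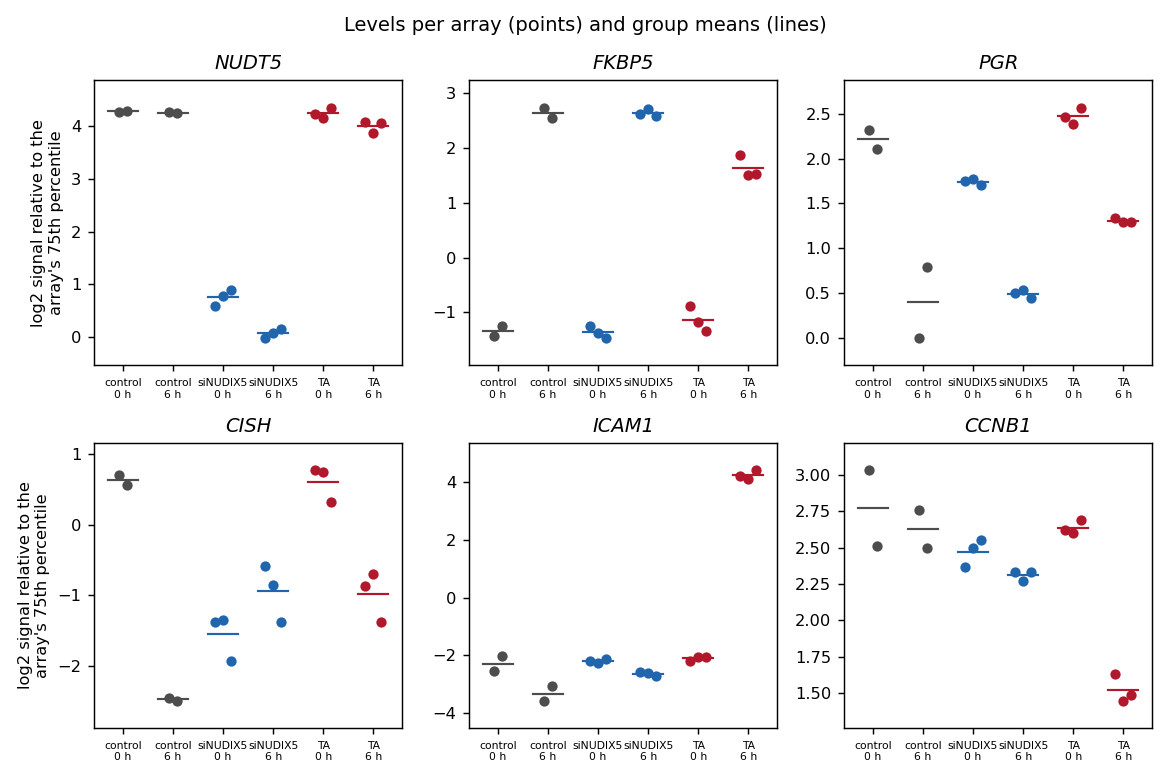
Log2 level (intensity relative to the 75th percentile of the array) of 6 genes by group, where each point is 1 array and each line is the mean of a group. NUDT5 is lower on the 6 siNUDIX5 arrays than on the 4 control arrays (mean 0.41 against 4.27), and ICAM1 is higher in TA_T6 than in TA_T0 (log2 change 6.32).

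The first question was which genes responded to 6 h of R5020 in control cells (2 arrays against 2). No arm had a group at 6 h without R5020, so hormone and time are not separated in any response given here. Of 26 measured progestin-induced genes, 19 rose and 2 fell (median log2 change 1.63; adjusted over the list alone, 20 and 2). Numbers adjusted over the list alone are given as "list alone" wherever they differ from those over all genes tested. SGK1, a kinase induced by steroid hormones, rose 112-fold (log2 6.80, SE 0.40, adjusted p = 2.78e-07). FKBP5, a chaperone of steroid receptors, rose by 3.99 (SE 0.16), the transcription factor STAT5A by 4.66 (SE 0.23) and the coagulation initiator F3 by 4.6 (SE 0.13). The receptor genes PGR and ESR1 fell, PGR by 1.82 (SE 0.19) and ESR1 by 1.16 (SE 0.11). SCRG1 rose at least 173-fold and KCNH1, a potassium channel, at least 22.7-fold, both dim before hormone, while the adhesion molecule AMIGO2 fell 35.6-fold (log2 −5.15, SE 0.16).

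Among the other lists in control cells, 12 of 26 DNA replication and G1/S genes rose and 0 fell (median 0.36; list alone, 14 and 0), including CCNE2, a cyclin of S-phase entry (1.36, SE 0.14), and the replication factor GINS2 (1.93, SE 0.11). Of 19 hypoxia-induced genes 9 rose and 2 fell (median 0.71, 0.19 to 0.84 over the alternatives; list alone, 11 and 2), with the glucose transporter SLC2A1 at 1.53 (SE 0.23). Of 16 luminal epithelial markers 8 fell and 0 rose (median −0.40), among them FOXA1, a pioneer factor of oestrogen receptor binding (−1.40, SE 0.14). Of 18 steroid receptors and cofactors 7 fell and 1 rose (median −0.19). Of 24 interferon-induced genes 6 fell and 1 rose (median −0.52; list alone, 7 and 1), with IFIT1 at −1.72 (SE 0.39). Ribosome biogenesis (3 of 22 rose) and heat shock genes (2 of 16 rose) each had a median of 0.20. Camera with its preset correlation called these 8 lists. The adjusted p was 7.25e-20 for progestin-induced genes (0.00318 with an estimated correlation), 1.42e-07 for replication (0.285 with an estimated correlation) and 1.47e-04 for hypoxia (0.266 with an estimated correlation). For the others the adjusted p with an estimated correlation lay between 0.154 and 0.8. The interferon call ended without control_T0 replicate 1 (median −0.29) or control_T6 replicate 2 (−0.19), the ribosome call without the same arrays (0.12 and 0.10) or with median scaling (0.20, adjusted p = 0.34) and the heat shock call without control_T0 replicate 2 (0.09) or control_T6 replicate 1 (0.00).

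In limma 3701 genes passed, 1910 raised and 1791 lowered. Slide 3, the only one with both times in control, gave a progestin list median of 1.59, and the slide as a block gave 3781 genes. Scaling to the median of each array gave 668 (69% raised, against 51.6%), array weights 2282 and a fit of these 4 arrays alone 468.

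The same question was asked in cells with siNUDIX5 (3 arrays against 3). There, 20 of 26 progestin-induced genes rose and 1 fell (median 1.56; list alone, 21 and 1). SGK1 rose by 6.35 (SE 0.32), FKBP5 by 4.0 (SE 0.13) and F3 by 4.47 (SE 0.11). PGR fell by 1.25 (SE 0.15), AMIGO2 by 3.79 (SE 0.13) and SOX2, a stem cell transcription factor, by 3.28 (SE 0.19). Of 22 ribosome biogenesis genes 10 rose and 1 fell (median 0.30; list alone, 13 and 1), and of the replication genes 10 rose and 1 fell (median 0.29; list alone, 13 and 2). Hypoxia-induced genes (6 rose, 2 fell, median 0.31; list alone, 10 and 3), luminal markers (8 fell, median −0.36; list alone, 9) and steroid receptors and cofactors (8 fell, median −0.25; list alone, 9 fell and 1 rose) were also called. So were heat shock genes (3 rose, median 0.09), the integrated stress response (5 rose, 0.11; list alone, 5 rose and 1 fell), glycolysis (3 rose, 0.10) and NUDIX hydrolases other than NUDT5 (4 fell, −0.18). Of these 10 lists, progestin-induced genes held with an estimated correlation (adjusted p = 0.00103), and the adjusted p of the others lay between 0.107 and 0.821 with an estimated correlation. The stress response, glycolysis and NUDIX calls ended with median scaling, the first and last also when TA_T6 replicate 2 was left out of it. The glycolysis call also ended without siNUDIX5_T0 replicate 1 or 2 (0.08 and 0.07) or siNUDIX5_T6 replicate 1 (0.06), and the stress response call without siNUDIX5_T6 replicate 3 (0.09).

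In this arm 3818 genes passed, 1812 raised and 2006 lowered, and 2370 of the 3701 control genes passed here with the same sign, where 324.2 would by chance. Across genes, which are not independent replicates, the 2 responses correlated at r = 0.648 (Spearman 0.468). Within slides 1, 2 and 3 the progestin median was 1.55, 1.60 and 1.53. The slide as a block gave 4271 genes, array weights 6231 and median scaling 720 (72.9% raised, against 47.5%). Median scaling without TA_T6 replicate 2 gave 58.8% raised.

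With TA the response to R5020 took in NF-kB target genes (3 arrays against 3). All 16 measured inflammatory NF-kB targets rose (median 2.85), among them ICAM1, a leukocyte adhesion molecule, by 6.32 (SE 0.14) and the inhibitor TNFAIP3 by 4.66 (SE 0.19). CCL5, a chemokine gene, rose at least 110-fold. Progestin-induced genes rose as well (21 of 26, 1 fell, median 2.28), with SGK1 at 5.31 (SE 0.32) and GREB1, a steroid-responsive gene, at 4.10 (SE 0.10). Of 26 mitosis genes 24 fell (median −0.94), such as the kinase AURKA by 1.86 (SE 0.12) and the checkpoint gene BUB1B by 2.32 (SE 0.10). FOXA1 fell by 3.96 (SE 0.11), GATA3, a luminal transcription factor, by 2.80 (SE 0.08) and SOX2 had a change of −5.42 (SE 0.19). The luminal markers as a list were not called with TA (5 rose, 5 fell, median −0.08; list alone, 6 and 5).

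Of 18 NRF2 antioxidant targets 11 rose and 1 fell (median 0.79), with the haem oxygenase HMOX1 at 4.87 (SE 0.15). Of 20 integrated stress and unfolded protein response genes 15 rose and 2 fell (median 0.92; list alone, 15 and 3), with ATF3 at 4.04 (SE 0.10) and DDIT3 at 2.60 (SE 0.14). Of 20 p53 targets 11 rose and 4 fell (median 0.49), with the cell cycle inhibitor CDKN1A at 2.55 (SE 0.14). Immediate early genes (10 rose, 2 fell, median 0.55), hypoxia-induced genes (14 rose, 2 fell, median 0.67) and ribosome biogenesis (11 rose, 3 fell, median 0.24, but −0.22 and no longer called with median scaling) lay above other genes. Replication genes (17 fell, 2 rose, median −0.48; list alone, 19 and 2), steroid receptors and cofactors (8 fell, 1 rose, median −0.23) and chromatin remodelling complexes (13 fell, 2 rose, median −0.30) lay below. Camera called these 12 lists. NF-kB targets (adjusted p = 3.29e-11, 0.0425 with an estimated correlation) and progestin-induced genes (6.62e-11, 0.0341 with an estimated correlation) held, and for the others the adjusted p lay between 0.0765 and 0.604 with an estimated correlation. The chromatin call ended with median scaling (−0.75, adjusted p = 0.0716), and the ribosome call also without TA_T6 replicate 1 (0.21). Over the alternatives the median was as low as 0.04 for p53 targets, 0.10 for immediate early and 0.22 for hypoxia-induced genes, each still called. Without TA_T6 replicate 2, the array with 42239 probes above background, the medians were 2.96 for NF-kB targets, −0.91 for mitosis, −0.46 for replication, 0.75 for NRF2 targets and 1.00 for the stress response.

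Here 11021 genes passed, 5353 raised and 5668 lowered. Within slides 1, 2 and 3 the NF-kB median was 2.98, 3.20 and 2.64, and the slide as a block gave 11587. Median scaling gave 6655 genes, 24.6% raised against 48.6%, with the median of all genes at −0.39 in place of 0.065 (−0.129 with quantile normalization). Without TA_T6 replicate 2 there were 10575.

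**Figure D2:**
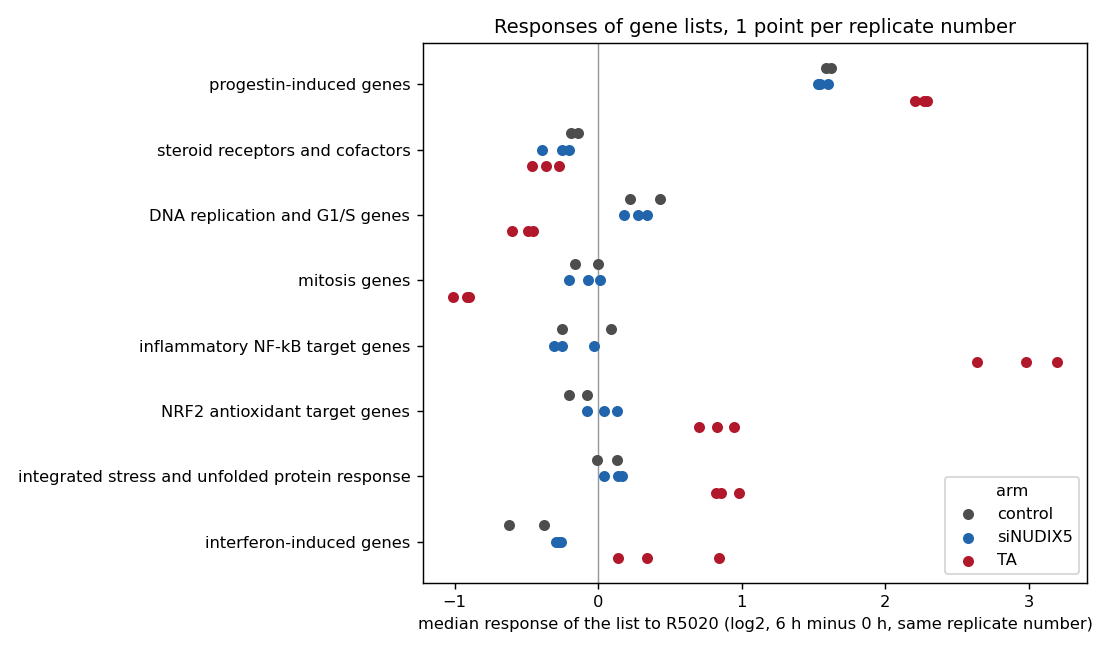
Median log2 response to R5020 (6 h minus 0 h) of 8 gene lists by arm, where each point is 1 pair of arrays with the same replicate number. NF-kB targets lie between 2.64 and 3.20 in the TA pairs and between −0.31 and 0.09 in the others, and progestin-induced genes lie at 1.53 or above in every pair.

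The next comparison asked which responses differed between siNUDIX5 and control cells. CISH, a feedback inhibitor of STAT5 signalling, fell by 3.1 in control and had a change of 0.62 with siNUDIX5, a difference of 3.72 (SE 0.37, adjusted p = 0.00162). It was already lower by 2.18 at 0 h with siNUDIX5. MYC fell by 0.55 in control and rose by 0.62 (difference 1.18, SE 0.12, adjusted p = 0.00162), and was lower by 0.74 at 0 h. The difference also passed for S100B, a calcium-binding protein gene that was well above background in control_T6 alone (adjusted p = 0.0135). The aldo-keto reductase gene AKR1C3 rose by 2.18 in control and by 0.77 with siNUDIX5 (difference −1.41, SE 0.14), and it was already higher by 1.75 at 0 h with siNUDIX5. STC2, a secreted glycoprotein, differed by 2.11 (SE 0.31), the chemokine receptor ACKR3 by −2.67 (SE 0.22) and the phosphatase DUSP1 by −1.04 (SE 0.20). At 0 h with siNUDIX5 STC2 was at −3.13, ACKR3 at −0.65 and DUSP1 at 0.96 relative to control.

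FKBP5, SGK1, STAT5A and F3 differed by 0.01 (SE 0.21), −0.45 (SE 0.51), −0.05 (SE 0.29) and −0.13 (SE 0.17), which did not pass. Of 26 progestin-induced genes, MYC and DUSP1 passed. Of 24 interferon-induced genes 1 rose (OASL, 1.21, SE 0.23; median 0.24). Of 20 oestrogen receptor targets 1 rose (STC2; median 0.18; list alone, 2 rose and 1 fell), and of 26 replication genes 0 passed (median −0.13). Camera called these 3 lists (adjusted p = 0.0298, 0.0323 and 0.0323) and none held, at adjusted p = 0.813, 0.251 and 0.813 with an estimated correlation. The strict filter ended all 3 calls, and median scaling, with or without TA_T6 replicate 2, those of oestrogen targets (0.25) and replication (−0.06). So did leaving out single arrays, with the interferon median at 0.07 without control_T0 replicate 1, −0.04 without control_T6 replicate 2 and 0.24 without siNUDIX5_T6 replicate 3. The oestrogen target median was 0.11 without control_T0 replicate 1, 0.17 without control_T6 replicate 1, 0.18 without siNUDIX5_T0 replicate 3 and 0.19 without siNUDIX5_T6 replicate 3. The replication median was −0.07 without control_T0 replicate 1, −0.08 without control_T6 replicate 1, −0.13 without siNUDIX5_T0 replicate 2, −0.12 without siNUDIX5_T0 replicate 3 and −0.13 without siNUDIX5_T6 replicate 3, and this call also ended with the slide as a block (−0.12).

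In total 160 genes passed, 62 with a more positive and 98 with a more negative response. Slide 3, the only one with all 4 groups, gave list medians of 0.22 for interferon-induced genes, 0.21 for oestrogen receptor targets and −0.17 for replication, and the slide as a block gave 152 genes. Leaving out each siNUDIX5 array in turn gave 75, 79 and 88 (T0 replicates 1 to 3) and 98, 87 and 106 (T6 replicates 1 to 3). Median scaling gave 15 (117 and 51.3% more positive, against 38.8%, without TA_T6 replicate 2), no filter 57, array weights 72, a trended robust prior 256 and a fit of the 10 arrays alone 50. STC2 and ACKR3 did not pass with median scaling.

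The response with TA was compared with that of control in the same way. ICAM1, down by 1.04 in control, differed by 7.36 (SE 0.23, adjusted p = 1.85e-08). The cytokine gene TNF differed by 7.76 (SE 0.39) and TNFAIP3 by 3.84 (SE 0.29), and of 16 NF-kB targets 14 had a more positive response and 0 a more negative one (median 2.94; list alone, 15). Of 26 mitosis genes 23 (median −0.93; list alone, 24) and of 26 replication genes 23 (median −0.83; list alone, 25) had a more negative response, such as BUB1B at −2.28 (SE 0.16) and MCM2, a subunit of the replicative helicase, at −1.02 (SE 0.16). The progestin-induced genes went both ways, with FKBP5 at −1.23 (SE 0.21), STAT5A at −1.36 (SE 0.29), ZBTB16 at −1.85 (SE 0.35), GREB1 at 1.79 (SE 0.17) and KLF4 at 2.42 (SE 0.35). EGFR, a growth factor receptor, rose by 1.48 in control and had a change of 0.07 with TA (difference −1.41, SE 0.19).

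HMOX1 (3.94, SE 0.24) and OSGIN1 (4.12, SE 0.24) were among 8 of 18 NRF2 targets with a more positive response (median 0.90; list alone, 9). Of 24 interferon-induced genes 11 were more positive and 0 more negative (median 0.93; list alone, 12 and 1), led among the named genes by the antiviral RSAD2 (6.04, SE 1.02). Immediate early genes (12 more positive, 1 more negative, median 0.96; list alone, 12 and 2), the integrated stress response (11 and 1, median 0.68; list alone, 11 and 2) and chromatin remodelling complexes (2 and 7, median −0.20) were also called. So were p53 targets (9 and 2, median 0.36; list alone, 9 and 3), whose median was −0.10 with median scaling, where the median of all genes was −0.376 in place of 0.082 (−0.097 with quantile normalization). With camera 9 lists were called. The adjusted p was 9.61e-13 for NF-kB targets (0.056 with an estimated correlation), 5.13e-12 for mitosis (0.247 with an estimated correlation), 1.5e-11 for replication (0.119 with an estimated correlation) and 1.42e-04 for NRF2 targets (0.0818 with an estimated correlation), and with an estimated correlation none held. The chromatin call ended with median scaling (−0.66, and −0.22 without TA_T6 replicate 2). Without TA_T6 replicate 2 the medians were 3.06 for NF-kB targets, −0.89 for mitosis, −0.77 for replication, 0.84 for NRF2 targets, 0.79 for interferon-induced and 0.89 for immediate early genes.

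A difference in response passed for 6211 genes, 2924 more positive and 3287 more negative with TA. Slide 3 gave list medians of 2.70 for NF-kB targets, −0.75 for mitosis and −0.90 for replication, and the slide as a block gave 6411 genes. Median scaling gave 1224 genes (26.7% more positive, against 47.1%), or 5520 with TA_T6 replicate 2 left out, an alternative chosen after seeing the data. Without that array and with the usual scaling there were 6257. No group had TA for the last 6 h without R5020, so the time in TA and the hormone are not separated.

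Set against each other, siNUDIX5 minus TA, 7704 responses differed, 3865 more positive and 3839 more negative. ICAM1 (−6.76, SE 0.20) and TNF (−6.70, SE 0.35) were more negative with siNUDIX5, as were CCL5 and the basal keratin KRT6B, both dim in TA_T0. The pluripotency factor NANOG, dim in siNUDIX5_T0 and TA_T6, was more positive. The lists were those that differed between TA and control, with opposite signs, at medians of −3.18 for NF-kB targets (16 of 16 genes), 0.94 for mitosis (23 of 26; list alone, 23 and 1 against it), 0.71 for replication (20 of 26), −0.77 for NRF2 targets (11 of 18), −0.72 for immediate early genes (10 of 20), −0.77 for the stress response (11 of 20; list alone, 12), −0.78 for interferon-induced genes (10 of 24; list alone, 11), 0.30 for chromatin remodelling (10 of 22; list alone, 12) and −0.50 for p53 targets (10 of 20). The p53 median was 0.03 with median scaling, where the median of all genes was 0.426 in place of −0.101 (0.106 with quantile normalization), and the chromatin call ended there (0.83, adjusted p = 0.0527). With an estimated correlation none of the 9 calls held, with adjusted p between 0.0584 and 0.735. Within slides 1, 2 and 3 the NF-kB median was −2.94, −3.44 and −2.97. The slide as a block gave 8391 genes and median scaling 2352 (77.2% more positive, against 50.2%).

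A further question was how siNUDIX5 and control cells differed before hormone (3 arrays against 2). The labels do not say what the control cells received, so transfection, lower NUDT5 and lower NUDT9 are not separated. Of 26 mitosis genes 12 fell (median −0.38; list alone, 14), including KIF20A, a mitotic kinesin, by 0.84 (SE 0.17) and the proliferation marker MKI67 by 0.65 (SE 0.16). Of 18 NRF2 targets 12 rose (median 0.47; list alone, 15 and 1 fell), with HMOX1 at 1.44 (SE 0.17) and AKR1C1 at 1.86 (SE 0.29). Cholesterol genes rose (12 of 19, median 0.50; list alone, 16), for example MSMO1 by 1.18 (SE 0.20) and INSIG1 by 0.87 (SE 0.21). Of 20 oxidative phosphorylation genes 8 rose (median 0.26; list alone, 14), of 16 heat shock genes 7 rose (median 0.31; list alone, 8) and of 19 nucleotide kinases 9 rose (median 0.30; list alone, 11 and 1 fell), among them AK1 at 0.59 (SE 0.10). Hypoxia-induced genes fell (8 of 19, 2 rose, median −0.29; list alone, 9 and 2), such as VEGFA, the vessel growth factor, by 0.81 (SE 0.11) and PFKFB3 by 1.76 (SE 0.19), as did 4 of 9 metallothioneins (median −0.26).

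Among single genes at 0 h the cytochrome CYP1A1 rose 12.4-fold (log2 3.63, SE 0.54, and 2.30 to 4.96 over the alternatives) and CRYM, which binds thyroid hormone, 8.77-fold (SE 0.12 on the log2 scale). SERPINA6, the corticosteroid-binding globulin, fell 12.1-fold (log2 −3.59, SE 0.15), STC2 fell 8.73-fold and TIMP3, a metalloproteinase inhibitor, at least 6.75-fold. In the NUDIX family NUDT9 fell by 2.22 (SE 0.09) and NUDT6 by 1.48 (SE 0.14), while NUDT14 rose by 0.99 (SE 0.11). Camera called the 8 lists (mitosis adjusted p = 4.04e-07, NRF2 targets 3.42e-06, oxidative phosphorylation 4.49e-05, cholesterol 0.000174), and none held, at adjusted p = 0.0833 for NRF2 targets and 0.433 to 0.593 for the others with an estimated correlation. The hypoxia call ended without control_T0 replicate 2 (−0.08), the metallothionein call without control_T0 replicate 1 (−0.19) and with median scaling (−0.10), and the nucleotide kinase call with median scaling (0.45).

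At 0 h 5340 genes passed, 2955 raised and 2385 lowered. On slides 1 and 3 the mitosis median was −0.19 and −0.66 and the NRF2 median 0.37 and 0.66, and the slide as a block gave 5506. Without control_T0 replicate 1 there were 3052, without the filter 3406 and with median scaling 346 (36.4% raised, against 55.3%, with the median of all genes at 0.196 in place of 0.045), or 7078 (73.8% raised) once TA_T6 replicate 2 was left out too.

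At 6 h of R5020 siNUDIX5 and control cells differed in 9 lists. Mitosis genes fell (12 of 26, median −0.44; list alone, 18) and NRF2 targets rose (11 of 18, median 0.70; list alone, 12), with AKR1C1 at 1.86 (SE 0.29). Of 19 hypoxia-induced genes 11 fell and 1 rose (median −0.58; list alone, 12 and 1), with VEGFA at −1.25 (SE 0.11), and of 9 metallothioneins 7 fell (median −0.50), with MT2A at −0.60 (SE 0.12). Oxidative phosphorylation (8 rose, median 0.19; list alone, 9), nucleotide kinases (6 rose, 0.17), heat shock (3 rose, 0.33; list alone, 1), ribosome biogenesis (8 rose and 1 fell, 0.15; list alone, 9 and 1) and cholesterol genes (4 rose, 0.29; list alone, 6) were called too. The adjusted p was 1.03e-06 for mitosis and 2.1e-05 for NRF2 targets (0.58 and 0.129 with an estimated correlation), and none of the 9 calls held with an estimated correlation. With quantile normalization the cholesterol, nucleotide kinase, oxidative phosphorylation and ribosome calls ended (medians 0.21, 0.09, 0.11 and 0.11), and with median scaling the metallothionein call as well (−0.28). The cholesterol, oxidative phosphorylation and ribosome calls also ended with normexp (0.19, 0.10 and 0.10) and the value table, and the cholesterol and ribosome calls with the strict filter. The cholesterol and ribosome calls ended without control_T6 replicate 1 (0.19 and 0.10), and the heat shock call without control_T6 replicate 2 (0.14). S100B was at least 7.22-fold lower and CYP1A1 12.9-fold higher (log2 3.68, SE 0.54).

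In all 5565 genes passed at 6 h, 3014 raised and 2551 lowered. On slides 2 and 3 the mitosis median was −0.30 and −0.50, and the slide as a block gave 6177. A fit of the compared groups alone gave 1932, no filter 3557 and median scaling 242 (median of all genes 0.206 in place of −0.013), or 7786 (80.1% raised, against 54.2%) once TA_T6 replicate 2 was left out too.

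TA before hormone was compared with control at 0 h. RNASE10 (at least 1.5-fold lower, adjusted p = 0.00615) and LOC100506220 passed, both above background in control_T0 alone, and 1583 genes had an unadjusted p below 0.05. RPS6KA2, a ribosomal S6 kinase, at 0.72 (SE 0.13, adjusted p = 0.418) and SPRY1, an inhibitor of growth factor signalling, at −0.73 (SE 0.14, adjusted p = 0.467) did not pass. Camera called 7 lists in which no member passed, with medians of 0.20 for the integrated stress response, 0.21 for hypoxia-induced genes, 0.22 for cholesterol, 0.14 for glycolysis, 0.14 for fatty acid synthesis, 0.10 for oestrogen receptor targets (list alone, 3 rose) and −0.25 for metallothioneins. None held, with adjusted p between 0.323 and 0.643 with an estimated correlation. Without control_T0 replicate 1 the calls of the stress response (0.04), hypoxia (0.05), cholesterol (−0.02), glycolysis (−0.08), fatty acid synthesis (0.02) and metallothioneins (−0.15) ended, and the oestrogen target call ended without control_T0 replicate 2 (0.16) or TA_T0 replicate 1 (0.06). It also ended with quantile normalization (0.12), median scaling (0.23) and the strict filter (0.10). The fatty acid call also ended without TA_T0 replicate 1 (0.10) or 3 (0.09), with median scaling (0.28), with the strict filter (0.14), with the replicate as a block (0.13) and with the slide as a block (0.13), where 2 genes passed. Median scaling ended the metallothionein call too (−0.12). With median scaling the median of all genes was 0.103 in place of −0.034. On slide 1 the medians were −0.03, 0.03, −0.09 and −0.16 for the stress response, hypoxia, cholesterol and glycolysis, and on slide 3 0.41, 0.29, 0.53 and 0.39. With limma's trended robust prior, the value table, normexp, the strict filter or the compared groups alone 0 genes passed, and 21, 191 and 1 did without control_T0 replicate 1, control_T0 replicate 2 and TA_T0 replicate 2.

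After 6 h of R5020 TA and control cells differed widely. ICAM1 was 186-fold higher (log2 7.54, SE 0.16) and TNF 153-fold (SE 0.28 on the log2 scale), CCL5 was at least 120-fold higher, and 15 of 16 NF-kB targets rose (median 3.00). Mitosis (23 of 26 fell, median −1.11; list alone, 25) and replication genes (23 of 26 fell, median −0.83) were lower, including TTK, a checkpoint kinase, at −1.98 (SE 0.13). SMAD6, an inhibitor of BMP signalling, fell 19.4-fold (log2 −4.28, SE 0.58). NRF2 targets (12 of 18 rose, median 0.78), the integrated stress response (12 rose, 1 fell, 0.77; list alone, 14 and 1), immediate early genes (14 and 2, 0.87), interferon-induced genes (12 and 1, 0.99; list alone, 13 and 1) and p53 targets (11 and 3, 0.36; list alone, 12 and 3) were higher. Metallothioneins (7 of 9 fell, 1 rose, −0.47) and chromatin remodelling complexes (10 of 22 fell, 2 rose, −0.22) were lower. The adjusted p was 1.96e-12 for NF-kB targets and for mitosis (0.0618 and 0.203 with an estimated correlation), and none of the 10 calls held with an estimated correlation. The chromatin call (adjusted p = 0.0487) ended without control_T0 replicate 1 or 2 (−0.22 each), control_T6 replicate 2 (−0.22) or TA_T6 replicate 2 (−0.23). Among the settings it held without the filter alone, with −0.24 for the slide as a block and −0.55 for median scaling. The metallothionein call ended without control_T6 replicate 1 (−0.42) or TA_T6 replicate 2 (−0.49), and with quantile normalization (−0.56), median scaling (−0.79), normexp (−0.56), the value table (−0.55) and the strict filter (−0.47).

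For TA at 6 h 8548 genes passed, 3959 raised and 4589 lowered. On slides 2 and 3 the NF-kB medians were 3.24 and 2.51 and the mitosis medians −1.08 and −1.09, and the slide as a block gave 8810. Without TA_T6 replicate 2 there were 8484. Median scaling gave 3193 (29.6% raised, against 46.3%), where the median of all genes was −0.308 in place of 0.013 (−0.122 with quantile normalization), and a fit of the compared groups alone 4864.

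**Figure D3:**
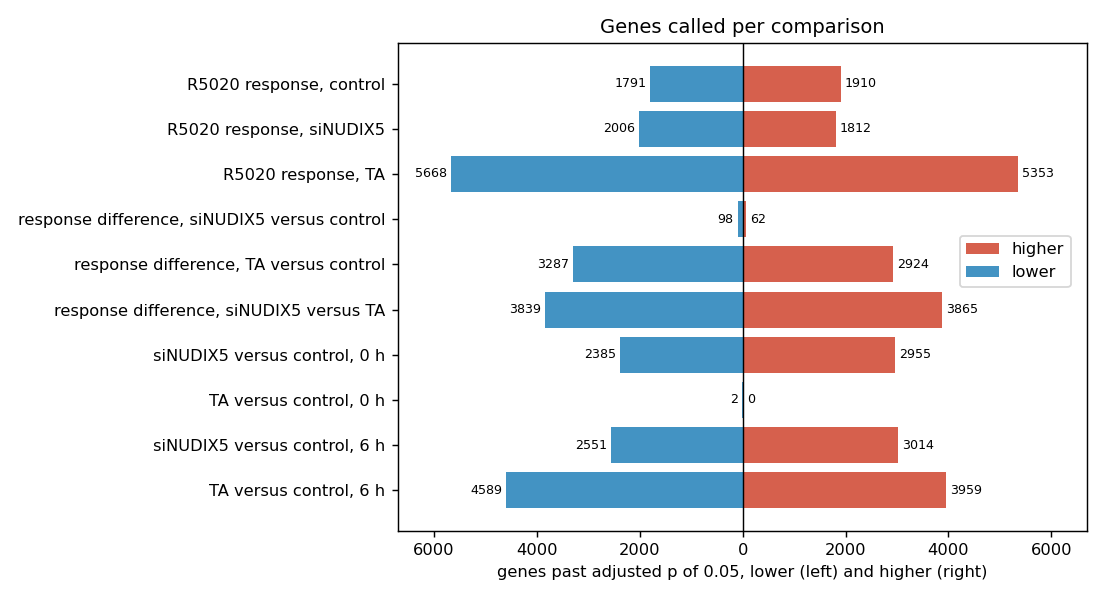
Number of genes with an adjusted p below 0.05 in each of the 10 comparisons, where bars to the right of 0 count raised genes and bars to the left lowered genes. The TA response has 5353 raised and 5668 lowered genes, and TA against control at 0 h has 0 and 2.

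The lists of poly(ADP-ribose) and NAD metabolism, basal and mesenchymal markers, stromal and blood cell markers and housekeeping genes were called in none of the 10 comparisons. In the poly(ADP-ribose) and NAD list, NAMPT, the rate-limiting enzyme of NAD salvage, rose with R5020 by 1.15 (SE 0.09) in control, 0.82 (SE 0.08) with siNUDIX5 and 1.70 (SE 0.08) with TA. PARP1, which makes poly(ADP-ribose), fell by 0.42 (SE 0.11) with siNUDIX5.

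The size of the response was compared between 2 arms over genes picked in the remaining arm. Over the 5353 genes raised and 5668 lowered with TA, the mean response was 0.221 with siNUDIX5 and 0.311 in control for raised genes (ratio 0.713, camera p = 0.0254, 0.0515 with an estimated correlation) and −0.191 and −0.24 for lowered genes (ratio 0.794, camera p = 0.00571, 0.0579 with an estimated correlation). With its sign turned to the direction of TA, it was 0.272 and 0.276 in the 2 control pairs and 0.193, 0.204 and 0.22 in the 3 siNUDIX5 pairs, a ratio of 0.749 over all these genes. Without control_T0 replicate 2 (0.799) or control_T6 replicate 1 (0.785) camera no longer called it. Over genes picked with siNUDIX5 the ratio of TA to control was 0.877, from raised genes (0.793, camera p = 0.00204, 0.13 with an estimated correlation) and not lowered ones (1.02, camera p = 0.202, 0.466 with an estimated correlation). It was no longer called without control_T0 replicate 1 (0.918), with quantile normalization (0.818) or with the strict filter (0.903). Over genes picked in control the ratio of siNUDIX5 to TA was 0.934 (lowered genes 0.849, camera p = 0.00181, 0.0285 with an estimated correlation; raised genes 0.991, camera p = 0.531). It turned to 1.27 with median scaling and was no longer called with quantile normalization (0.928).

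Because siNUDIX5 and TA were compared with the same control arrays, their effects correlate across genes with no shared effect. Their covariance was 0.0845 at 6 h and 0.0561 at 0 h, against 0.0691 and 0.0685 in simulations in which neither arm had an effect. The values of r were 0.182 and 0.325 against 0.602 and 0.598, but an effect in 1 arm alone lowers r. At 6 h 891 genes were higher and 924 lower in both arms (548.4 and 538.1 by chance if the arms shared no control), and 1190 passed with opposite signs. No chance value was computed for opposite signs, and the shared control alone raises the numbers with the same sign. These counts therefore do not show a shared effect.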

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

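The explanations tested here were chosen after the results were seen, except for the 3 counts over other splits of the arrays, though the settings they use were planned before the data, apart from scaling to the median of spots above background and median scaling without TA_T6 replicate 2.

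Responses to R5020 differed between TA and control for 6211 genes, with medians of 2.94 for NF-kB targets, −0.93 for mitosis, −0.83 for replication, 0.93 for interferon-induced, 0.90 for NRF2, 0.68 for stress response, 0.36 for p53, 0.96 for immediate early and −0.20 for chromatin remodelling genes. The array TA_T6 replicate 2 alone does not account for it, as 6257 genes differed without that array, and scaling as the whole cause of the number is argued against by 5520 genes under median scaling with TA_T6 replicate 2 left out (1224 with it, as the median SE over the 6211 rose from 0.17 to 0.51 and the median absolute difference was 0.91 and 1.07). Relative to all genes, the medians closest to 0 under quantile normalization, normexp and the value table were 1.89 for NF-kB, −0.85 for mitosis, −0.72 for replication, 0.75 for interferon-induced, 0.56 for NRF2, 0.70 for stress response, 0.58 for immediate early and 0.26 (SD of the TA pairs 0.21) for p53 genes. All 8 lists were called under every scaling with camera's preset correlation. Median scaling and scaling to the median of spots above background subtract 1 constant per array. They leave a list's median relative to all genes as it is, so they do not test these shifts. The values under quantile normalization, normexp and the value table argue against scaling as the whole cause of them. Scaling stays open as a cause for chromatin remodelling (−0.12), whose call ended with median scaling. Quantile normalization, normexp and the value table share a quantile step, so they are not independent checks. With an estimated correlation none of these lists was called. Of 12 blood and stromal markers CD68 (3.95, SE 0.54) and COL1A1 (1.10, SE 0.11) were higher in TA_T6 than in control_T6. Such cells would make them higher, but DCN (−0.58, SE 0.15) and CD14 (−0.40, SE 0.13) were lower. The median of the markers was −0.14 (SD 1.36), against 3.00 for NF-kB targets. The markers stand for different cell types, so cells of 1 type would raise only some of them. The median therefore cannot exclude such cells as a cause. A change in transcription of the genes of these 8 lists with TA may add to the response as a hypothesis, but no group had TA for 6 h without R5020, so hormone and time in TA cannot be told apart, and within the TA arm the real split of 6 arrays gave 11021 genes and the highest other 5, with 1 of 10 splits as large, too few splits for a share below 0.05.

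Responses with siNUDIX5 differed from control for 160 genes, with medians of 0.24 for interferon-induced genes, 0.18 for oestrogen receptor targets and −0.13 for replication genes. A different level before hormone that was gone at 6 h would show as genes that differed at 0 h and not at 6 h. Of the 160 genes 37 did, while 50 differed at 6 h and not at 0 h and 73 at both. Of all genes tested 24.5 percent differed at 0 h. A level before hormone that partly persisted would fall under both, so these counts leave it open as a cause. The slides argue against placement of the control arrays as the cause, with 152 genes under a slide block. Dim probes make up 17 of the 160, where 9.9 percent of all genes tested were dim in the same way. Within the siNUDIX5 arm the real split gave 3818 genes and the highest other 0, with 1 of 10 splits as large, again too few splits. An effect of siNUDIX5 on these responses may be part of it as a hypothesis, with single siNUDIX5 arrays left out giving 75 to 106 genes and median scaling 15.

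The mean response was smaller with siNUDIX5 than in control over genes called with TA (ratio 0.749). Under the other scalings the ratio was 0.673 to 0.752, so scaling as the cause finds no support, and over genes above background on all arrays it was 0.76. With 1 control array left out it was 0.708 to 0.799, below 0.9, a bound set after the values were seen. The pairs lay apart (0.272 and 0.276 against 0.193, 0.204 and 0.22), but 2 pairs against 3 allow no exact p below 0.1, and camera lost the call with an estimated correlation. A smaller response to R5020 over these genes may follow siNUDIX5, a hypothesis found and tested on the same arrays. Their mean responses in control were small, 0.311 for raised and −0.24 for lowered genes. The progestin-induced list had medians of 1.63 in control and 1.56 with siNUDIX5.

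Of the other ratios, 0.877 for TA over control was not called with an estimated correlation (p = 0.13 and 0.466), quantile normalization or the strict filter, and 0.934 for siNUDIX5 over TA turned to 1.27 with median scaling. Responses with siNUDIX5 differed from those with TA for 7704 genes. Of 100 drawn assignments (of 200) only the real one gave a count as large, a share below 0.05. The highest other was 7157, from an assignment that kept the 6 h arrays in place and exchanged 2 pairs of 0 h arrays. Such exchanges test any difference between the arms at either time, so chance is not excluded for the difference in response. The list medians for that difference were 0.71 for replication, 0.94 for mitosis, 0.30 for chromatin remodelling, −0.78 for interferon-induced, −3.18 for NF-kB, −0.77 for NRF2, −0.77 for stress response, −0.50 for p53 and −0.72 for immediate early genes.

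Single genes stood out because the difference between 2 responses passed. For siNUDIX5 against control the log2 difference was 3.72 for CISH, 3.12 for RNASE10, 3.00 for CYP2B6, 2.77 for PCDH18, 2.42 for HERC6, 2.34 for ATF6B, 2.11 for STC2, 1.83 for C5AR2, 1.62 for FGD3, 1.61 for CDC42EP3, 1.59 for CYP2S1 and 1.41 for CAMKK1. It was −5.00 for S100B, −3.11 for LINC00841, −2.68 for ADORA2B, −2.67 for ACKR3, −2.45 for AP5B1, −2.32 for CLSTN3, −2.23 for ENSA, −2.16 for FLJ30901, −2.07 for PFDN6, −1.99 for GGT7, −1.83 for SERPINE2 and −1.76 for PRPH2. RNASE10, PCDH18, S100B, LINC00841 and ADORA2B were not well above background in 3 of the 4 groups, so the size of their difference depends on the background. With the value table it was 0.58, 0.63, −1.80, −0.52 and −0.45, and of these 5 S100B alone passed there. Other genes shrank too. Over the alternatives the difference was as small as 0.54 for HERC6, 0.65 for CDC42EP3, −0.89 for FLJ30901 and −0.78 for PRPH2. HERC6, ATF6B, AP5B1, GGT7, CAMKK1 and FLJ30901 failed under several settings and with several single arrays left out. Of the alternatives that tested each gene, AP5B1 failed under 23 of 32, HERC6 under 23 of 31 and ATF6B under 22 of 32. GGT7 failed under 19 of 32, CAMKK1 under 15 of 32 and FLJ30901 under 14 of 31. The calls of AP5B1, HERC6, ATF6B and GGT7 therefore ended under most alternatives. ADORA2B failed under 7 settings, PRPH2 under 6, CDC42EP3 and LINC00841 under 5 each, RNASE10, PCDH18, SERPINE2, C5AR2, FGD3 and PFDN6 under 3 each and CYP2B6 under 2. STC2, CYP2S1, ACKR3, CLSTN3 and ENSA failed with median scaling alone, and CISH and S100B passed under every alternative that tested them.

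For TA against control the difference was 9.29 for CCL5, 7.76 for TNF, 7.36 for ICAM1, 6.36 for CCL4, 6.34 for THEMIS2, 6.25 for MAFF, 6.19 for RTP4, 6.09 for CREB5, 6.08 for IL36G, 6.04 for RSAD2, 5.71 for SAA1 and 5.70 for SAA2. It was −4.90 for RANBP3L, −4.60 for ZBED2, −4.38 for SMAD6, −4.30 for FLRT3, −4.14 for DEFB132, −4.13 for S100B, −4.08 for TMEM266, −4.05 for MYLK4, −4.01 for G6PC1, −3.94 for MPPED2, −3.69 for C10orf114 and −3.66 for ARHGEF4. MPPED2 failed without control_T0 replicate 1 and with only the compared groups in the fit, and both MPPED2 and ARHGEF4 failed with the mean of their probes. CCL5, THEMIS2, IL36G, SAA1, SAA2, FLRT3, DEFB132, S100B, TMEM266 and G6PC1 were not well above background in at least 1 of these 4 groups, so the size depends on the background here too. With the value table it was 5.13 for CCL5, 3.45 for THEMIS2, 2.36 for IL36G, 1.72 for SAA1 and 1.91 for SAA2. Over the alternatives it was as small as −2.24 for FLRT3 and DEFB132, −1.62 for S100B and −2.07 for G6PC1. Genes not in this group shrank too, such as CCL4 (to 3.49), RTP4 (to 3.57) and RSAD2 (to 2.88). For siNUDIX5 against TA the difference was 5.76 for RANBP3L, 5.23 for MYLK4, 4.64 for NANOG, 4.42 for CDC42EP3, 4.21 for MPPED2, −7.79 for CCL5, −6.76 for ICAM1, −6.70 for TNF, −6.24 for KRT6B and −6.12 for IL10RA. NANOG, CCL5, KRT6B and IL10RA were dim in at least 1 of these groups, with 1.18, −4.86, −1.66 and −2.73 from the value table, and MPPED2 failed with the mean of its probes (0.74).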

How the results depend on the processing

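The normalization to the median of spots above background on every array, and median scaling without TA_T6 replicate 2, were chosen after seeing the data. The replicate block, the slide block, the random slide block, quantile normalization and the mean of probes kept every gene count within 1.5 times its value, and the 85 list calls numbered 68 to 103 over all alternatives. No named gene that passed reversed. CEP170 for TA at 0 h, which did not pass, was at 0.42 and at its lowest −0.01 over the alternatives. Median scaling kept 63 of the 85 list calls (77 with TA_T6 replicate 2 left out), the strict filter 76, quantile normalization 78, normexp and the value table each 80, the slide block 82 and the replicate block 83. With an estimated correlation 4 of the 85 held. NUDT5 has 1 probe, so each probe on its own was not run. The level of a dim gene is limited by background, and 14862 genes were not tested.

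Median scaling gave 668, 720 and 6655 genes for the responses in control, siNUDIX5 and TA, 15, 1224 and 2352 for the differences siNUDIX5 against control, TA against control and siNUDIX5 against TA, 346 and 242 for siNUDIX5 at 0 and 6 h and 3193 for TA at 6 h, and it turned the size ratio of siNUDIX5 over TA to 1.27. With TA_T6 replicate 2 left out too the same counts were 3500, 3511, 9959, 117, 5520, 7068, 7078, 7786 and 7782, so that array takes part in the drop, and on it the 75th percentile lay 2.72 above the median on the log2 scale, against 3.84 to 4.17 elsewhere.

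For TA at 0 h 0 genes passed with normexp, the value table, the strict filter, a trended robust prior or the compared groups alone. Without the filter the siNUDIX5 difference had 57 genes and siNUDIX5 at 0 and 6 h 3406 and 3557, where more genes were tested. Array weights gave 2282 in control, 6231 with siNUDIX5 and 72 for the siNUDIX5 difference, and a trended robust prior 256 for that difference. The compared groups alone, with fewer arrays in the fit, gave 468 in control, 50 for the siNUDIX5 difference, 1932 for siNUDIX5 at 6 h and 4864 for TA at 6 h. A 1.5-fold minimum left 2371, 1977 and 7164 for the responses in control, siNUDIX5 and TA, 2448 and 2576 for siNUDIX5 at 0 and 6 h and 5441 for TA at 6 h. The ratio of TA over control was 0.818 with quantile normalization and 0.903 with the strict filter, and that of siNUDIX5 over TA 0.928 with quantile normalization, each no longer called. The causes of the changes in this paragraph were not tested.

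With 1 array left out in turn, counts ran from 2940 to 4158 in control, 2799 to 4345 with siNUDIX5, 9877 to 11214 with TA, 75 to 236 for the siNUDIX5 difference, 5416 to 6257 for the TA difference, 6680 to 7985 for siNUDIX5 against TA, 3052 to 6025 for siNUDIX5 at 0 h, 1 to 191 for TA at 0 h, 3833 to 6315 for siNUDIX5 at 6 h and 7206 to 8696 for TA at 6 h. Ratios ran from 0.703 to 0.799 (siNUDIX5 over control), 0.829 to 0.918 (TA over control) and 0.902 to 0.991 (siNUDIX5 over TA). The cholesterol median for TA at 0 h ran from −0.02 to 0.48 and the glycolysis median from −0.08 to 0.40, each lowest without control_T0 replicate 1.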

Other observations

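The lists of basal and mesenchymal markers (4 rose, 4 fell, median 0.35), heat shock genes (6 rose, 7 fell, −0.13), fatty acid synthesis (3 rose, 5 fell, −0.04) and cholesterol genes (9 rose, 2 fell, 0.26) were not called for the response with TA. Single members, picked after seeing their values, went both ways. Over 6 h of R5020 with TA KRT17 (2.63, SE 0.34) rose, while VIM (−0.95, SE 0.15), CDH2 (−0.66, SE 0.15) and TAGLN (−1.17, SE 0.13) fell. Of the heat shock genes HSPB8 (2.27, SE 0.18) and CRYAB (2.33, SE 0.18) rose, and HSPA8 (−1.57, SE 0.23) and HSPA1A (−1.0, SE 0.22) fell.

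In the NUDIX family NUDT7, a peroxisomal coenzyme A hydrolase, fell with R5020 in each arm, by 0.87 (SE 0.08) in control, 0.75 (SE 0.07) with siNUDIX5 and 1.07 (SE 0.07) with TA. NUDT18 fell by 0.86 (SE 0.08), 0.56 (SE 0.07) and 0.89 (SE 0.07). With siNUDIX5 at 0 h NUDT17 (0.64, SE 0.08) and NUDT8 (0.71, SE 0.10) rose.

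The array TA_T6 replicate 2 stood apart in several measures of the scanner software. Its negative-control mean was 39.5 (25.7 to 30.7 elsewhere), its spatial residual 8.11 (3.76 to 5.77 elsewhere) and its weight in a weighted fit 0.239 (0.513 to 2.759 elsewhere). The first 2 principal components held 37.7 and 17.8 percent of the variance.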
